A study of Homo sapiens with 25 samples.

How the data were processed

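Gene expression was measured in 25 samples of the human B-cell lymphoma line Karpas 422, 5 in each of 5 groups: untreated control cells, and cells given 100 or 200 µCi of bismuth-213 on rituximab for 46 min or 24 h. The deposited table gives 1 log2 expression value per probe set and array of a 1-colour Affymetrix array, including 47 of the maker's control probe sets. The authors named the affy package for making these log2 values, and its version, background correction, normalization and summary method are not given in the sources used here. Deposited values lay between 3.79 and 13.19. Array medians differed by less than 0.1, but interquartile ranges ran from 1.38 to 1.76. Because these ranges differed by more than the limit of 0.2 set before the data were examined, values were quantile normalized between arrays with limma (normalizeBetweenArrays), and deposited and median-centred values were kept as alternatives. The median gene shifted by less than 0.1 in each of the 4 comparisons with the control under all 3 scalings.

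Probe sets were matched to genes with the supplied probe table and current gene names by gene number. Of the probe sets that are not control probe sets, 7840 were listed with 1 gene, 388 with several genes and 518 with none, and 7838 matched a current gene. For 122 genes with more than 1 probe set the brightest was used, leaving 7713 genes. No genomic coordinates were used.

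A linear model with 5 group means was fitted to each gene with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes; 20 residual degrees of freedom per gene before moderation). The 9 comparisons were each treated group against the control, 200 against 100 µCi at each time, 24 h against 46 min at each activity, and the interaction of activity and time. The Benjamini-Hochberg adjusted p was computed over all genes in each comparison, with a threshold of 0.05, two-sided. Gene groups were 29 lists fixed before the data were examined, with 819 memberships of which 634 were measured. The lists were p53 targets, DNA damage sensing and repair, pro-apoptotic and anti-apoptotic genes, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, immediate early genes, NF-κB targets, interferon-stimulated genes, endoplasmic reticulum stress and amino acid response, heat shock proteins, oxidative stress response, B-cell identity and B-cell receptor, germinal-centre genes, plasma-cell genes, MHC class II, MHC class I and antigen processing, complement regulators, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, MYC and ribosome biogenesis, proteasome subunits, splicing factors, and markers of T and NK cells, of myeloid cells, and of epithelial cells and fibroblasts. Lists with at least 5 measured genes were tested with camera (preset correlation 0.01, and again with the correlation estimated per list) and with fry (directional and mixed).

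Genes named in the text followed a rule written before the data were examined. In each comparison with the control it took, of the called genes whose treated values all lay above or all below the control values, the 8 largest rises and the 8 largest falls. From each list with a camera adjusted p under 0.05, or with 3 or more called genes, it took up to 4 called members with the largest change, and it always took MS4A1, CDKN1A, MDM2, GADD45A, BAX and FAS. Another pair of genes that the rule always takes was not analysed here. For the remaining comparisons it took the 5 largest rises and falls, or the 3 smallest p-values where none were called. The rule gave 267 gene results, of which the text prints those that a reader needs. Genes named outside the rule are said to be chosen after their values were seen.

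The fit was tested on simulated data with 200 of 7713 genes changed, in 10 simulations per comparison. For 100 µCi at 46 min against the control it recovered 87.8% of changes of 0.5 log2, 96.9% of changes of 1 and 99.1% of changes of 2, with 8.7 false calls on average. For the interaction it recovered 77.9%, 94.0% and 99.1%. A list shifted by 0.5 log2 was called by camera in 20 of 20 simulations, and 2 of 560 tests of other lists were called. The simulated errors were independent between genes and no simulated array stood apart, so these rates need not hold for the real arrays.

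The overlap of responses was compared with the number given by independence, with 50 simulations in which comparisons shared nothing but their control arrays, and with correlations across genes after dividing the controls between the comparisons. Other splits of the samples were counted for each comparison, 100 drawn with a fixed seed. Outlying arrays were sought with Dixon's ratio.

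Alternatives chosen before the data were examined were each array left out in turn, replicate number as a block, deposited values, median centring, all probe sets, the mean of a gene's probe sets, filters at the 20th percentile and at the median level, adjusted p under 0.01, a minimum change of 1.5-fold, limma's treat at 1.2-fold, trend and robust variances, array weights, a fit of the compared groups alone, and Welch's test. Fits without the 3 arrays that stood apart, with a term for them, and on deposited values without them were added after seeing the data. Probe sets with several genes or none were left out of the comparisons, since their signal cannot be given to a single gene. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.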

Results

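The series profiled Karpas 422 (K422) cells, a human B-cell lymphoma line, after exposure to rituximab carrying bismuth-213. Rituximab is an antibody against CD20, the surface protein encoded by MS4A1, and bismuth-213 emits alpha particles, so the conjugate delivers densely ionising radiation to cells that display CD20. Cells received an activity of 100 or 200 µCi and were sampled at 46 min or at 24 h. Each of these 4 groups and an untreated control group had 5 arrays, 25 in all. The labels give no incubation time for the control cells and list no cells given antibody without bismuth-213. They do not say whether the 5 replicates of a group were separate cultures, so the p-values below measure the spread between these samples, which may be technical. Amplified RNA from 500 ng was hybridised to a 1-colour Affymetrix array, from which 7713 genes were tested. Deposited log2 intensities ran from 3.79 to 13.19, with array medians of 5.49 to 5.54 and interquartile ranges of 1.38 to 1.76. The number of arrays limits the precision of each value.

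Of the 25 arrays, 3 stood apart from the rest: control replicate 4, replicate 5 of 100 µCi at 46 min and replicate 2 of 200 µCi at 46 min. Across probe sets their deposited values correlated with one another at r = 0.989 to 0.995, and with the other 22 arrays at 0.916 to 0.943, while those 22 correlated among themselves at 0.972 to 0.998. On these 3 arrays UCHL1, a deubiquitinase, read 9.91 to 10.0 log2 against 5.37 to 5.68 on the other 12 control and 46 min arrays. VIM, which encodes the filament protein vimentin, read 9.18 to 9.47 against 5.34 to 5.55, and MT1X, a metallothionein, read 6.04 to 6.22 against 9.66 to 10.2. These 3 genes were chosen after their values were seen. MS4A1 read 8.73 to 8.85 on them, inside the 8.24 to 9.16 of the other 12, but of 21 genes of B-cell identity 5 lay above and 6 below the other 12 on all 3 arrays. All 25 arrays stay in the values below, and the number of genes called in each comparison is also given without these 3.

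**Figure D1:**
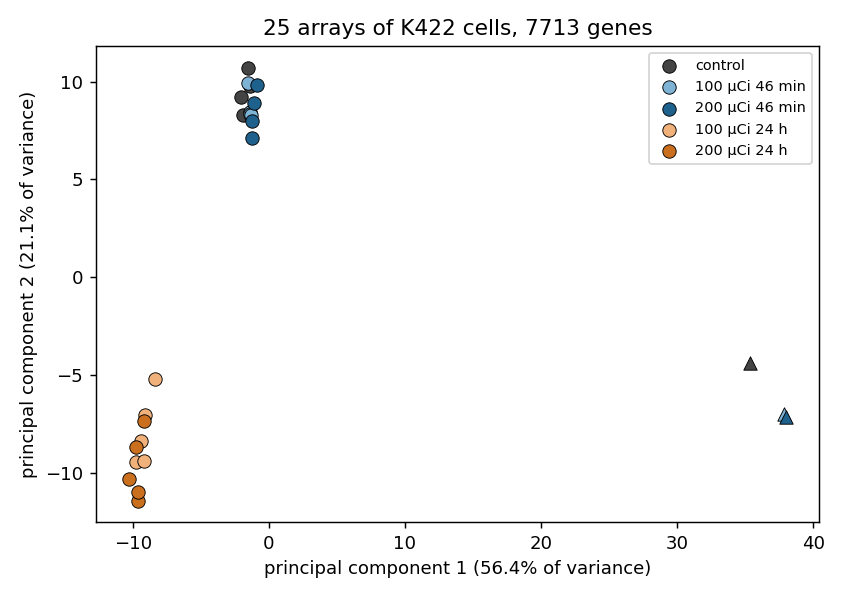
Scores of the 25 arrays on the first principal components of 7713 genes, component 1 on the horizontal axis (56.4% of variance) and component 2 on the vertical axis (21.1%). Colours mark the 5 groups, and triangles mark control replicate 4, 100 µCi 46 min replicate 5 and 200 µCi 46 min replicate 2, which lie apart on component 1.

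The first question was which transcripts had changed by 46 min, one half-life of the isotope, at the lower activity. NFKBIA, which encodes the inhibitor of NF-κB that NF-κB itself induces, rose from 7.41 ± 0.44 log2 in the control to 9.80 ± 0.68 (mean ± SD, n = 5), a change of 2.39 (SE 0.33). PPP1R15A, a stress-induced regulator of translation, rose by 1.16 (SE 0.18), and TNFSF9, the ligand of the costimulatory receptor 4-1BB, rose by 0.54 (SE 0.07). JUNB, a subunit of the AP-1 transcription factor, rose by 0.49 (SE 0.09). In each of these 4 genes all 5 treated arrays lay above all 5 controls, as the naming rule required, and limma gave adjusted p of 6.7e-04, 0.00194, 6.7e-04 and 0.0105. Among falls, RHOH, a small GTPase of lymphocytes, fell by 0.51 (SE 0.08), although that call was lost on deposited values, and SLC30A4, a zinc transporter, fell by 0.19 (SE 0.03). SLC30A4 averaged 4.77 log2 in the control and 4.58 in this group, under the median of every array. Its fall is therefore a small change at low signal.

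Immediate early genes, which switch on within minutes of a stimulus without new protein synthesis, were shifted upward as a list at 100 µCi and 46 min. Of 29 measured, 4 were higher and 0 lower by limma (7 and 0 adjusted over the list alone), against 12 higher without the 3 arrays, and the list's median change was 0.29. The set test camera gave an adjusted p of 3.75e-09 (adjusted p = 0.0013 with an estimated correlation). FOSB, another AP-1 subunit, rose by 1.09 (SE 0.23, limma adjusted p 0.0362), and by 1.18 (adjusted p 3.94e-05) with the 3 arrays left out. The call with all arrays was lost without control replicate 2, 4 or 5 or without 100 µCi 46 min replicate 1, 2, 3 or 4, where the adjusted p was 0.0825, 0.0677, 0.0591, 0.0748, 0.0984, 0.0817 and 0.0745. The p53 targets CDKN1A (0.14, SE 0.29; −0.07 with the 3 arrays left out), MDM2 (−0.04, SE 0.05), GADD45A (0.02, SE 0.11), BAX (0.09, SE 0.17) and FAS (0.02, SE 0.34) did not pass the threshold, nor did MS4A1 (0.08, SE 0.10). MDM2 averaged 4.23 to 4.29 log2 across the 5 groups, under the array medians of 5.49 to 5.54. This is near the lowest deposited value of 3.79, so its flat reading says little about a response. The list of 25 p53 targets had 0 members called and a camera adjusted p of 0.0658 (0.182 with the 3 arrays left out), but it passed fry, which does not compare a list with other genes (adjusted p 0.00393).

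In all, limma called 34 of 7713 genes at 100 µCi and 46 min, 24 higher and 10 lower, and 1047 genes had an unadjusted p under 0.05. Without the 3 arrays the count was 140 (96 higher, 44 lower), 31 of them among the 34, and on deposited values without further normalization it was 140 (105 higher, 35 lower), 30 of them among the 34. Single arrays moved the count: to 15, 16 and 16 without replicates 2, 3 and 4 of this group, to 19, 17 and 56 without control replicates 1, 2 and 3, and to 55 and 81 without replicates 2 and 5 of 200 µCi at 46 min.

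At 200 µCi the same question was asked of the higher activity at 46 min. NFKBIA rose to 10.1 ± 0.65 log2 (n = 5), a change of 2.66 (SE 0.33), PPP1R15A rose by 1.14 (SE 0.18) and JUN, an AP-1 subunit, rose by 0.88 (SE 0.17). DNAJB1, a cochaperone of HSP70, rose by 0.67 (SE 0.12), NFE2L2, which encodes the oxidative stress regulator NRF2, rose by 0.67 (SE 0.14), and JUNB rose by 0.61 (SE 0.09). RHOH fell by 0.72 (SE 0.08). For these 7 genes the 5 treated arrays lay wholly on one side of the 5 controls, as the naming rule required. Their limma adjusted p was 1.32e-04, 0.00121, 0.0136, 0.00513, 0.0177, 5.19e-04 and 5.32e-05. Smaller falls were seen for PFDN2 (−0.42), a prefoldin subunit, INPPL1 (−0.39), a lipid phosphatase, SNRNP70 (−0.35), a component of the U1 spliceosomal particle, and TRAP1 (−0.31), a mitochondrial chaperone, and these 4 calls were lost under median centring.

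Of the 29 immediate early genes, 6 were higher and 0 lower at 200 µCi and 46 min by limma (11 and 0 adjusted over the list alone), against 14 higher without the 3 arrays. Their median change was 0.31, and camera gave an adjusted p of 2.45e-09 (adjusted p = 0.00115 with an estimated correlation). FOSB rose by 1.15 (SE 0.23, limma adjusted p 0.0165). Among 36 splicing factors 1 was higher and 2 were lower (the same 1 and 2 adjusted over the list alone), with no shift of the list as a whole (camera adjusted p 0.321). CDKN1A (0.24, SE 0.29; 0.04 with the 3 arrays left out), MDM2 (−0.02, SE 0.05), GADD45A (0.05, SE 0.11), BAX (−0.12, SE 0.17), FAS (0.02, SE 0.34) and MS4A1 (0.21, SE 0.10) did not pass. MDM2 again read near the lowest values on the arrays.

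Here limma called 59 of 7713 genes, 31 higher and 28 lower (52.5% higher), and 998 had an unadjusted p under 0.05. Deposited values gave 33, of which 28 were higher and 5 lower (84.8% higher) and 26 were among the 59, and leaving out the 3 arrays gave 350 (175 higher, 175 lower), 57 of them among the 59. Without replicate 2 or 5 of this group the count was 109 or 115.

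**Figure D2:**
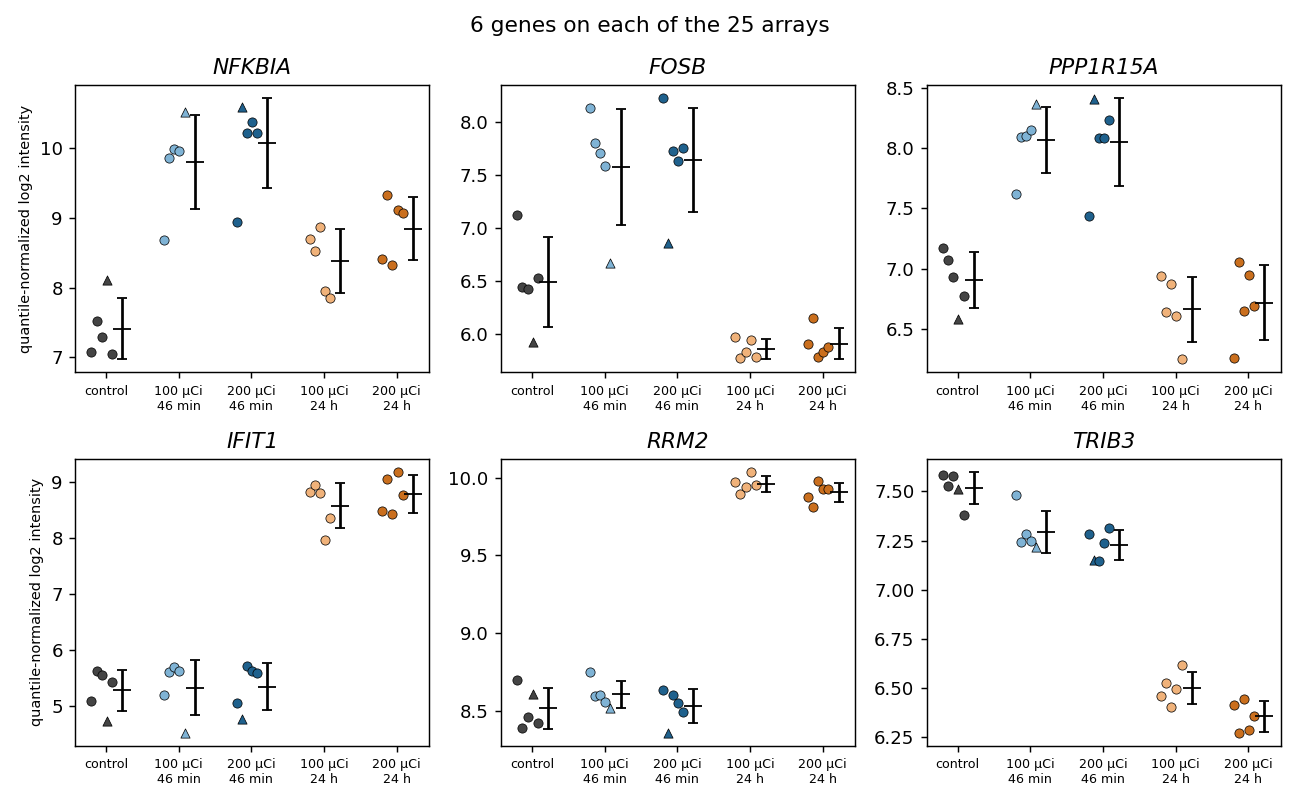
Quantile-normalized log2 intensity (vertical axes) of NFKBIA, FOSB, PPP1R15A, IFIT1, RRM2 and TRIB3 on each array, by group (horizontal axes). Points are arrays, triangles are the 3 arrays that stood apart, and dashes with bars are the group mean and SD of 5 arrays. NFKBIA averaged 7.41 in the control and 9.80 and 10.1 at 46 min, whereas IFIT1 averaged 5.28 in the control and 8.58 and 8.79 at 24 h.

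The next comparisons asked which transcripts differed from the control after 24 h. Interferon-stimulated genes, the antiviral genes that type I interferon switches on, held the largest changes at both activities. IFIT1, which binds foreign RNA, rose from 5.28 ± 0.37 log2 to 8.58 ± 0.41 at 100 µCi and to 8.79 ± 0.34 at 200 µCi (n = 5). These were changes of 3.30 and 3.51 (SE 0.24), with limma adjusted p of 1.87e-09 and 6.61e-10. IFI27, an interferon-induced mitochondrial protein, rose by 3.18 and 3.53 (SE 0.28), RIGI, a sensor of viral RNA, by 2.99 and 3.58 (SE 0.25), and IFIT3, a partner of IFIT1, by 2.59 and 3.06 (SE 0.20). All 5 treated arrays lay above all 5 controls for each of these genes at each activity, as the naming rule required. Of 28 list members measured, 22 were higher at 100 µCi and 24 at 200 µCi (26 and 26 adjusted over the list alone), and none were lower by limma. The list's median change was 1.39 and 1.69, with camera adjusted p of 1.65e-28 and 1.3e-32 (adjusted p = 0.0151 and 0.00618 with an estimated correlation). Control replicate 4, one of the 3 arrays that stood apart, read low for part of this list: 16 of its 28 genes were lower on all 3 such arrays than on the other 12 control and 46 min arrays. With the 3 arrays left out, 26 and 27 members were higher.

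Genes of antigen presentation by MHC class I rose as a list at 24 h. Of 14 measured, 7 were higher and 1 lower at 100 µCi, and 9 were higher and 0 lower at 200 µCi (8 and 1, and 10 and 0, adjusted over the list alone). HLA-B, a class I heavy chain, rose by 0.92 and 1.12 (SE 0.09), HLA-C, another heavy chain, by 0.77 and 0.96 (SE 0.12), and PSMB9, a subunit of the immunoproteasome, by 1.09 and 1.00 (SE 0.26). With the 3 arrays left out PSMB9 rose by 0.85 (SE 0.06) at 100 µCi. The camera adjusted p was 1.94e-06 and 4.21e-09 (adjusted p = 0.0158 and 0.00365 with an estimated correlation; 0.0545 and 0.0278 with it and without the 3 arrays). MHC class II genes, which present antigen to helper T cells, went both ways. Of 11 measured, 2 were higher and 2 lower at 100 µCi, and 2 were higher and 3 lower at 200 µCi (2 and 2, and 2 and 4, adjusted over the list alone; camera adjusted p 0.393 and 0.137). HLA-DMB, which loads peptides onto class II molecules, fell by 0.56 and 0.58 (SE 0.06), whereas CTSS, the protease cathepsin S, rose by 0.51 (SE 0.12) at 200 µCi.

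Genes of the G1/S transition and DNA replication rose at 24 h. Of 28 measured, 19 were higher at each activity and 0 were lower (24 and 22 higher adjusted over the list alone), with median changes of 0.48 and 0.57. RRM2, a subunit of the enzyme that makes deoxyribonucleotides, rose by 1.44 and 1.39 (SE 0.06), CCNE2, cyclin E2, by 1.37 and 1.38 (SE 0.10), and CDC6, which licenses replication origins, by 0.94 and 0.99 (SE 0.11). The camera adjusted p was 1.28e-23 and 5.33e-23 (adjusted p = 0.00193 and 0.00222 with an estimated correlation). These genes also tended to be high on the 3 arrays that stood apart, where 16 of the 28 exceeded the other 12 control and 46 min arrays, and without those arrays 28 and 27 were higher at 24 h.

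Among 33 genes of DNA damage sensing and repair, 10 were higher at 100 µCi and 12 at 200 µCi, with 1 lower at each (11 and 12 higher, 2 and 1 lower, adjusted over the list alone). BRCA1, a factor of homologous recombination, rose by 1.14 and 1.19 (SE 0.07), its partner BARD1 by 0.52 and 0.56 (SE 0.11), and RPA3, a subunit of the protein that coats single-stranded DNA, by 0.51 and 0.44 (SE 0.06). The camera adjusted p was 3.82e-06 and 2.97e-07 (adjusted p = 0.00572 and 0.00222 with an estimated correlation; 0.0784 and 0.0433 with it and without the 3 arrays). Of 25 p53 targets, 6 and 5 were higher and 0 lower (the same numbers adjusted over the list alone), with median changes of 0.07 and 0.06. DDB2, a damage recognition factor, rose by 0.63 and 0.62 (SE 0.11), and PPM1D, the phosphatase that damps p53 signalling, by 0.53 and 0.37 (SE 0.10). The p53 list had camera adjusted p of 0.00741 and 0.0423 (adjusted p = 0.0181 and 0.0594 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, did not pass (0.07 and 0.19, SE 0.29). With the 3 arrays left out its changes were 0.19 and 0.31 (SE 0.06), which passed with limma adjusted p of 0.0165 and 1.91e-04. MDM2 (0.02 and −0.03, SE 0.05), GADD45A (0.05 and 0.07, SE 0.11) and FAS (0.37 and 0.43, SE 0.34; 0.02 and 0.08, SE 0.06, with the 3 arrays left out) did not pass. MDM2 read near the lowest values on the arrays here too, so its flat reading says little. BAX passed at 100 µCi (0.50, SE 0.17, limma adjusted p 0.047; 0.40 and 0.0219 with the 3 arrays left out) but not at 200 µCi (0.07). The call was lost with replicate number as a block (adjusted p 0.0709). It was also lost, with adjusted p of 0.0518 to 0.138, on leaving out control replicate 4 or 5, 100 µCi replicate 1, 2, 3 or 4 at 46 min or 2, 3, 4 or 5 at 24 h, or 200 µCi replicate 1 or 3 at 46 min or 1, 2, 3 or 5 at 24 h.

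Mitotic genes were split at 24 h. Of 30 measured, 3 were higher and 7 lower at 100 µCi, and 5 were higher and 8 lower at 200 µCi (the same numbers adjusted over the list alone; camera adjusted p 0.393 and 0.497). CDC20, an activator of the anaphase-promoting complex, fell by 1.33 and 1.34 (SE 0.22), whereas CCNA2, cyclin A2, rose by 0.66 and 0.57 (SE 0.07). The list's median was −0.13 and −0.10, but 0.07 and 0.00 on deposited values, where 6 were higher at each activity and 3 and 5 were lower.

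Of 19 genes of the endoplasmic reticulum stress and amino acid response, 5 were lower at 24 h at 100 µCi and 8 at 200 µCi, with 1 higher at each (7 and 10 lower, 1 and 2 higher, adjusted over the list alone). TRIB3, a pseudokinase induced by ATF4, fell by 1.02 and 1.17 (SE 0.05), and ATF4, the transcription factor that leads this response, fell by 0.83 and 0.84 (SE 0.12). The camera adjusted p was 0.0186 and 0.00487 (adjusted p = 0.094 and 0.0505 with an estimated correlation), and on deposited values it was 0.219 and 0.0185 with 2 and 5 genes lower. Among 23 oxidative stress genes 7 and 5 were higher and 1 and 3 lower (9 and 7, and 2 and 3, adjusted over the list alone; camera adjusted p 0.00194 and 0.00566; adjusted p = 0.104 and 0.156 with an estimated correlation). SQSTM1, an autophagy receptor, rose by 0.94 and 1.18 (SE 0.13), and PRDX1, a peroxidase, by 0.53 and 0.51 (SE 0.07), while TKT, an enzyme of the pentose phosphate pathway, fell by 0.63 and 0.63 (SE 0.07).

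Cytosolic ribosomal protein genes had 14 and 13 of 47 lower and 1 higher at each activity (14 and 14 lower and 1 higher adjusted over the list alone), with medians of −0.08 and −0.06 and camera adjusted p of 0.00194 and 0.00436 (adjusted p = 0.142 and 0.192 with an estimated correlation). On deposited values 3 and 7 were lower, 0 were higher and the medians were −0.16 and −0.21, the same direction. RPL10A, a large-subunit protein, fell by 0.33 and 0.47 (SE 0.08), the first of these calls being lost on deposited values. Of 17 genes of MYC and ribosome biogenesis, 7 and 8 were lower and 1 higher at each activity (9 and 9 lower and 1 higher adjusted over the list alone; camera adjusted p 0.00194 and 2.69e-04; adjusted p = 0.142 and 0.0934 with an estimated correlation). On deposited values 0 and 5 were lower, and the camera adjusted p was 0.219 and 0.00335. At 200 µCi MYC, a transcription factor of cell growth, fell by 0.82 (SE 0.16), and ODC1, which starts polyamine synthesis, fell by 0.78 (SE 0.09).

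Of 28 subunits of the proteasome, the main protein-degrading complex, 12 and 10 were higher and 0 lower (14 and 14 higher adjusted over the list alone), with medians of 0.18 and 0.19. PSMA3, a core subunit, rose by 0.63 and 0.64 (SE 0.15), and PSMA5, another, by 0.43 and 0.46 (SE 0.06). The camera adjusted p was 4.15e-07 and 2.88e-07 (adjusted p = 0.0553 and 0.0545 with an estimated correlation). Of 16 cholesterol synthesis genes 4 and 7 were lower and 0 higher (5 and 8 lower adjusted over the list alone), with camera adjusted p of 0.00166 and 0.00104 (adjusted p = 0.392 and 0.318 with an estimated correlation). SCD, a fatty acid desaturase, fell by 0.71 and 0.78 (SE 0.17), and DHCR7, which makes cholesterol from its direct precursor, fell by 0.63 (SE 0.14) at 200 µCi. On deposited values 0 and 3 of these genes were lower, and SCD at 100 µCi no longer passed. On the 3 arrays that stood apart 9 of the 16 exceeded the other 12 control and 46 min arrays.

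NF-κB targets had 4 and 5 of 25 higher and 1 and 2 lower (4 and 6, and 1 and 2, adjusted over the list alone; camera adjusted p 0.278 and 0.0816). TNF, the inflammatory cytokine, rose by 1.08 and 1.35 (SE 0.12), and LTA, lymphotoxin alpha, by 1.02 and 1.24 (SE 0.25). LTA read 5.62 log2 on control replicate 4, against 7.03 to 7.59 on the 12 control and 46 min arrays that did not stand apart. With the 3 arrays left out LTA rose by 0.71 (SE 0.09) at 100 µCi. NFKBIA was still above the control, by 0.97 and 1.44 (SE 0.33, limma adjusted p 0.0461 and 0.0032; 0.00349 and 9.18e-05 with the 3 arrays left out). The call at 100 µCi was lost, with adjusted p of 0.0513 to 0.119, on leaving out control replicate 1, 2, 3 or 5, 100 µCi replicate 2, 3 or 4 at 46 min or 1, 2 or 3 at 24 h, or 200 µCi replicate 3 or 4 at 46 min or 4 or 5 at 24 h. In the B-cell identity list 3 and 4 of 21 were lower and 0 higher (the same numbers adjusted over the list alone; camera adjusted p 0.278 and 0.123). BLK, a kinase of the B-cell receptor pathway, fell by 0.57 and 0.63 (SE 0.13). CD81, a tetraspanin membrane protein, fell by 0.46 and 0.69 (SE 0.06), the first of these calls being lost on deposited values, where 1 and 2 list members were lower and 2 and 0 higher. MS4A1, the antibody's target, read 0.25 and 0.18 (SE 0.10) above the control without passing, and at 100 µCi it passed on deposited values (0.50, limma adjusted p 0.00325) and without the 3 arrays (0.29, 0.0422).

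At 24 h limma called 1209 of 7713 genes at 100 µCi (593 higher and 616 lower, 49.0% higher) and 1283 at 200 µCi (632 and 651, 49.3% higher). The split by direction depended on scaling: deposited values gave 1237 genes with 82.6% higher and 1094 with 74.6% higher. Without the 3 arrays the counts were 1860 (925 higher, 935 lower) and 1927 (949 higher, 978 lower). All treated values lay above all control values for 428 and 473 called genes and below them for 357 and 424. The labels assign no control to the 24 h time, so these changes cover treatment and any difference in time in culture.

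**Figure D3:**
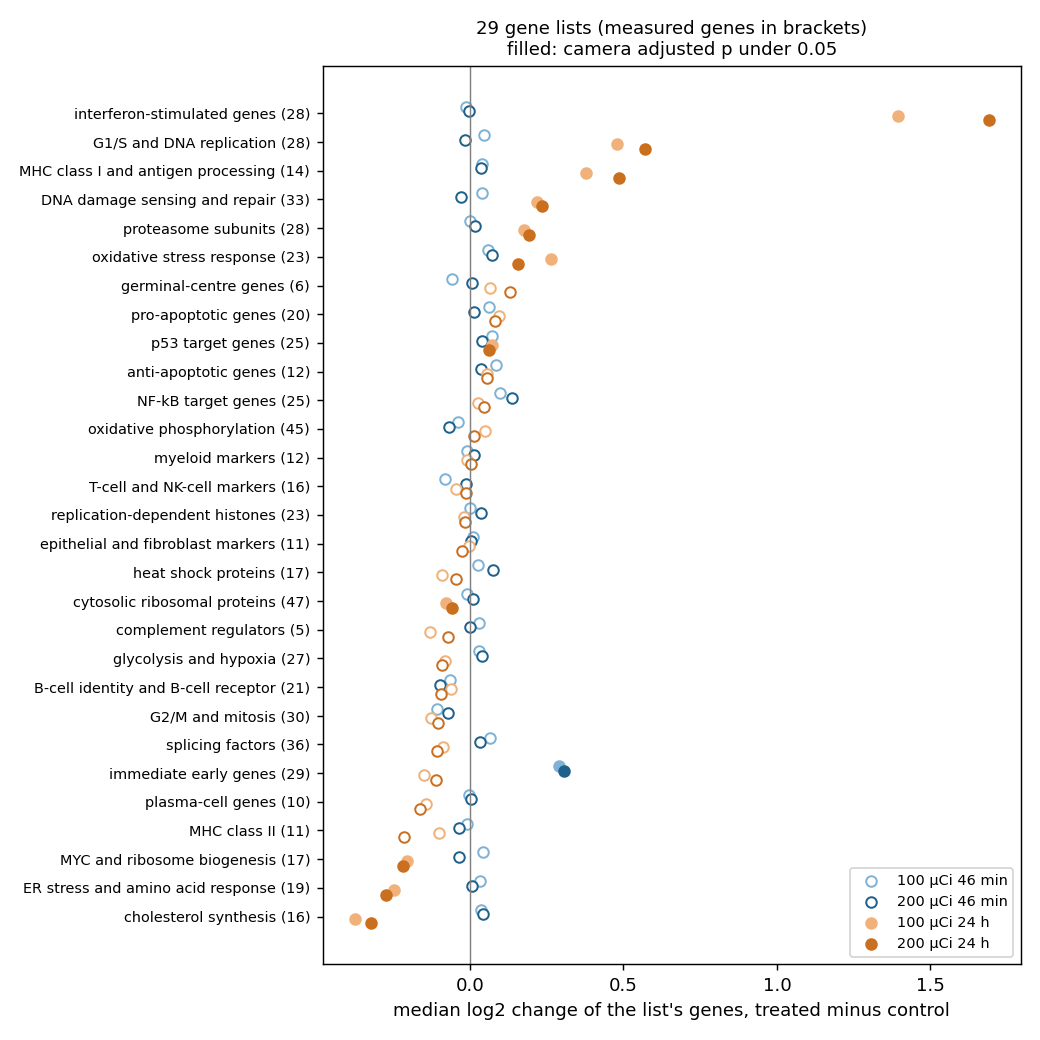
Median log2 change against the control (horizontal axis) of each of 29 gene lists (vertical axis, measured members in brackets) in the 4 comparisons, 1 point per list and comparison. Filled points had a camera adjusted p under 0.05 with the preset correlation. Immediate early genes sat at 0.29 and 0.31 at 46 min, interferon-stimulated genes at 1.39 and 1.69 at 24 h, and mitotic genes at −0.13 and −0.10, against 0.07 and 0.00 on deposited values.

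Doubling the activity was compared at each time. At 46 min limma called 4 genes: RPL9, a ribosomal protein, was higher at 200 than at 100 µCi by 0.30 (SE 0.04) and ARPC3, an actin-nucleating subunit, by 0.28 (SE 0.05), while PFDN2 fell by 0.45 (SE 0.07) and SNRNP70 fell by 0.28 (SE 0.05). Their adjusted p was 0.00259, 0.0161, 0.00259 and 0.0161, and on deposited values PFDN2 alone of the 4 passed. The count was 2 without 100 µCi 46 min replicate 2, without replicate 3 and without 200 µCi 46 min replicate 5, 7 without 200 µCi 46 min replicate 4, and 15 without the 3 arrays. At 24 h PPIB, a prolyl isomerase of the endoplasmic reticulum, was the 1 gene called, falling from 8.37 ± 0.23 at 100 µCi to 7.63 ± 0.09 at 200 µCi (mean ± SD, n = 5), a change of −0.74 (SE 0.10, limma adjusted p 0.00142). The actin 3′ minus 5′ difference, a measure of RNA quality, was 0.32 ± 0.29 log2 at 100 µCi, highest at 0.82 on replicate 1, and 0.80 ± 0.20 at 200 µCi, and whether it bears on the calls between these groups was not tested. This difference was 0.95 ± 0.70 in the control, and 0.67 ± 0.20 and 0.76 ± 0.21 at 46 min after 100 and 200 µCi. Its bearing on the comparisons of 100 µCi at 24 h with the control and with 46 min was not tested either. The count at 24 h was 68 without the 3 arrays, and 7, 2, 5, 2, 4 and 3 without 100 µCi 24 h replicate 1, 200 µCi 24 h replicate 1 or 3, 200 µCi 46 min replicate 2, and control replicate 4 or 5. None of the 3 arrays belongs to a 24 h group, so they act on this count only through the shared estimate of spread. The count of 1 with all arrays therefore does not show that the other genes were alike at both activities. Interferon-stimulated genes had a median of 0.17 more at 200 than at 100 µCi at 24 h with 0 of 28 members called by limma (1 adjusted over the list alone). The camera adjusted p was 1.08e-04 (adjusted p = 0.939 with an estimated correlation), and that of MHC class I genes was 0.00164 (adjusted p = 0.459 with an estimated correlation).

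The times were then compared directly at each activity. From 46 min to 24 h FOS, an AP-1 subunit, fell by 1.91 and 1.89 (SE 0.51), DUSP1, a phosphatase of MAP kinases, fell by 1.80 and 1.87 (SE 0.47), and FOSB fell by 1.72 and 1.73 (SE 0.23). NFKBIA fell by 1.43 (SE 0.33) at 100 µCi, and PPP1R15A fell by 1.33 (SE 0.18) at 200 µCi. The limma adjusted p of FOS was 0.0152 and 0.0149, and that of FOSB 2.15e-05 and 1.31e-05. Of 29 immediate early genes, 11 and 12 were lower at 24 h and 1 higher at each activity (16 and 18 lower, 1 and 2 higher, adjusted over the list alone). Camera adjusted p was 9.75e-08 and 2.01e-06 (adjusted p = 0.00239 and 0.00302 with an estimated correlation). IFIT1 rose by 3.26 and 3.44 (SE 0.24), and 21 and 23 of 28 interferon-stimulated genes were higher (26 and 27 adjusted over the list alone). In total limma called 766 genes at 100 µCi (438 higher, 328 lower, 57.2% higher) and 912 at 200 µCi (535 higher, 377 lower, 58.7% higher). Deposited values gave 720 with 71.8% higher and 866 with 72.2% higher, and leaving out the 3 arrays gave 1417 and 1501.

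Whether the change between times depended on activity was tested as an interaction. By limma 0 genes passed and 320 had an unadjusted p under 0.05, and each alternative setting and test tried also gave 0. The smallest p-values belonged to MED15, a Mediator subunit (0.27, SE 0.06), RBM5, a splicing regulator (0.36, SE 0.08), and TAX1BP1, an autophagy receptor (0.23, SE 0.06), each with adjusted p 0.818.

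The overlap of the calls was measured for genes called in the same direction in a pair of comparisons. Both activities shared 15 genes at 46 min, 14 higher and 1 lower, where independence would give 0.0965 and 0.0363. That overlap was 9 without 100 µCi 46 min replicate 3 or without control replicate 2, 26 without 200 µCi 46 min replicate 5, and 66 without the 3 arrays. At 24 h they shared 880, 472 higher and 408 lower, where independence would give 48.6 and 52.0, and none went opposite ways; with the 3 arrays left out they shared 1431. The comparisons share their control arrays, which by itself makes changes alike: across genes the changes correlated at r = 0.747 at 46 min and 0.953 at 24 h, against 0.504 and 0.496 in simulations where the control was all they shared. With the controls divided between the activities, r was −0.18 to 0.19 at 46 min and 0.63 to 0.78 at 24 h, and 0.38 to 0.47 and 0.83 to 0.89 with the 3 arrays left out. Genes are not independent replicates in these correlations. In the simulations the median number shared in the same direction was 0. They held no changed genes, so almost none could be called, and that median cannot be set against the overlaps counted here.

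Across times, 24 genes moved the same way at 46 min and 24 h at 100 µCi (18 higher, 6 lower; 1.85 and 0.799 by independence). At 200 µCi 34 did (17 higher, 17 lower; 2.54 and 2.36 by independence) and 2 went opposite ways. Across genes the changes correlated at r = 0.291 and 0.276, below the 0.50 and 0.50 of simulations where the control was all they shared. Their covariance, which is not divided by the spread of the changes, was 0.00842 and 0.00903, above the simulated 0.00724 and 0.00725. The simulations held no changed genes, so the lower r does not show that the times shared less than their control. With the controls divided, r was −0.33 to 0.26 and −0.30 to 0.28, and 0.15 to 0.26 and 0.17 to 0.25 with the 3 arrays left out. The 24 became 10, 11 and 10 without 100 µCi 46 min replicates 2, 3 and 4, 12, 11 and 43 without control replicates 1, 2 and 3, and 55 without 200 µCi 46 min replicate 5. The 34 became 59 and 60 without 200 µCi 46 min replicates 2 and 5. Without the 3 arrays the overlaps across times were 82 and 198, and 7 and 18 genes went opposite ways.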

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

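The tests of why 3 arrays stood apart and of the interferon-stimulated genes, the removal of other sets of 3 arrays, and the count of probe sets without a single gene name were chosen after the results were seen, while the sample splits were chosen before theirs.

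Control replicate 4, 100 µCi 46 min replicate 5 and 200 µCi 46 min replicate 2 shared a profile across cell genes. All 3 were at least 4-fold above every other control and 46 min array for 27 genes and 4-fold below for 15, 42 in all. Sex-linked genes (XIST and a set of Y-linked genes) were left out of these counts, so the counts do not cover all tested genes. The higher genes included CXCR4, a chemokine receptor, and CD48, a lymphocyte adhesion protein, and the lower ones included ISG15, an interferon-induced ubiquitin-like protein, all chosen after their values were seen. RNA degradation is argued against by actin probe sets, where 0 of the 3 exceeded the highest 3′ minus 5′ difference of the other 12 (0.865 at most against 2.10), and array scaling by r of at most 0.943 with the other 22 after quantile normalization, against at least 0.975 among those 22. A different source or passage of the cells may account for the profile, but the 27 higher genes reach the number set for it while the 15 lower ones lie between the numbers set for and against it, so it stays open, and the design gives no biological group that these arrays share.

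More genes were called at 46 min without those 3 arrays, 140 against 34 at 100 µCi and 350 against 59 at 200 µCi. Of 65 sets of 1 control and 2 treated arrays at 46 min, only the actual 3 (1 of 65 at each activity) gave as many when removed, the highest other counts being 113 and 141 and the medians 19.5 and 37. The other sets held none of the 3 arrays, and sets with some of them were not tried. Because the 3 were picked for standing apart, a fall in spread on their removal was likely beforehand. The median residual SD fell from 0.0938 with 25 arrays to 0.0830 with 22. The spread these arrays add is therefore a candidate explanation of the lower counts with all arrays.

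Interferon-stimulated genes were higher at 24 h than in the control. Scaling is argued against as the cause, since at least 24 of 28 members passed at either activity on deposited or median-centred values, and so is the low control array, since at least 26 passed without the 3 arrays. Time in culture cannot be told apart from treatment, because 0 of 5 control arrays were labelled as 24 h, and radiation and antibody binding remain untested as biological explanations.

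Several array measures lay far from the rest of their group, and chance marks about 1 in 20 groups this way. The median of control replicate 1 was 5.54, against 5.51 to 5.52 for the others. The interquartile range of 100 µCi 46 min replicate 5 was 1.57, against 1.63 to 1.65. The 3′ minus 5′ difference of the GAPDH control probe sets was 0.999 log2 on control replicate 5, against −0.05 to 0.20, and 0.575 on 100 µCi 24 h replicate 1, against −0.12 to 0.05.

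Of 152 named genes, 25 had 1 outlying control array, 23 of them control replicate 4. At 46 min 49 did so at 100 µCi, 39 on replicate 5, and 32 at 200 µCi, 29 on replicate 2, while at 24 h 9 and 7 did so, with at most 4 and 3 on one array. Chance would mark about 1 in 20 of these as well.

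The change from control differed between times, by limma's test of the difference, for 766 genes at 100 µCi and 912 at 200 µCi, led by interferon-stimulated genes such as IFIT1 and by FOS and FOSB. Among 906 probe sets without a single gene name, left out of the gene comparisons, 65 were higher and 86 lower than the control at 24 h after 100 µCi. After 200 µCi 61 were higher and 95 lower, by the same limma fit over all probe sets. Of the higher ones, 48 and 49 had all treated values above all control values. Of the 7713 tested genes, 593 and 632 were higher and 616 and 651 lower.

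Splits of the same samples into other groups tested chance, with 100 drawn per comparison, the real one included. They treat each array as a separate culture, which the labels do not state, so they cannot exclude a chance difference between cultures. For 100 µCi at 46 min (34 genes, highest other 19), 100 µCi at 24 h (1209 and 193), 200 µCi at 24 h (1283 and 52), and 24 h against 46 min at 100 µCi (766 and 38) and 200 µCi (912 and 25), only 1 of the 100 reached the count, which is under the 0.05 level for a chance division of these arrays. For 200 µCi at 46 min 4 of 100 did (59 genes, highest other 114), and 4 of 100 did for activity at 46 min (4 and 13) and at 24 h (1 and 6), also under that level although other splits gave more genes. The splits with 13 and 6 genes gave several times the real counts, and whether a structure of the samples other than activity lies behind them was not tested. The interaction had 0 genes (highest other 1), a count that all 100 reach whatever the data, so the splits say nothing about it.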

How the results depend on the processing

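The fits without the 3 arrays that stood apart, with a term for them, and on deposited values without them were chosen after the data were seen. Named genes were followed under the replicate block, deposited values, median centring, the filter above the median level, the mean of probe sets, those 3 fits and the removal of each array, and none changed direction past the threshold. The other settings were run for counts or lists only. Of 267 named gene results 241 passed the threshold. Under deposited values 183 of these still passed and 58 did not, under median centring 59 did not, without the 3 arrays 240 did, of the 229 tested above the median level none were lost, and 51 were lost on leaving out at least 1 array. Of the 26 that had not passed, 3 passed without the 3 arrays. A filter on array signal (genes above the median level) tests how far low signal limits these counts, and it moved the count at 200 µCi and 46 min to 95 by testing fewer genes. Except where construction shows it, the cause was not tested.

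Counts are given in the order 100 µCi at 46 min, 200 µCi at 46 min, 100 µCi at 24 h, 200 µCi at 24 h, activity at 46 min, activity at 24 h, time at 100 µCi and time at 200 µCi, where limma called 34, 59, 1209, 1283, 4, 1, 766 and 912. Without the 3 arrays they were 140, 350, 1860, 1927, 15, 68, 1417 and 1501, with a term for those arrays 391, 580, 2018, 2059, 47, 71, 1442 and 1561, and with array weights 277, 280, 1967, 1991, 19, 109, 1649 and 1390. Welch's test gave 0, 0, 468, 565, 0, 0, 318 and 318, with fewer degrees of freedom per gene. Stricter criteria gave fewer by construction: adjusted p under 0.01 gave 9, 21, 656, 707 and 2 in the first 5 and 439 and 518 for time, a change of at least 1.5-fold gave 4, 10, 190, 222, 0, 169 and 208 with activity at 24 h at 1, and treat at 1.2-fold gave 1, 2, 122, 176, 0, 0, 103 and 143.

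Deposited values gave 140, 33 and 1 for both activities at 46 min and their difference, and median centring gave 133, 29 and 1. Deposited values without the 3 arrays gave 224 and 96 at 46 min, 29 for activity at 24 h and 1195 for time at 100 µCi. For 200 µCi at 46 min all probe sets gave 107 and the filter at the 20th percentile 101. Trend and robust variances gave 2 for activity at 46 min, and fitting the compared groups alone gave 0 and 6 at 46 min and 0 and 81 for activity. The interaction stayed at 0 by limma and Welch's test in every setting, with 320 at unadjusted p under 0.05.

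Overlaps in the order both activities at 46 min, both at 24 h, both times at 100 µCi and both at 200 µCi were 15, 880, 24 and 34. Without the 3 arrays they were 66, 1431, 82 and 198, and with a term for those arrays 162, 1539, 223 and 315. Median centring gave 25 for both activities at 46 min and 84 and 18 for both times at 100 and 200 µCi, deposited values gave 26, 83 and 19, and deposited values without the 3 arrays gave 63 for both activities at 46 min and 132 for both times at 100 µCi. The filter above the median level gave 53 for both times at 200 µCi.

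Gene lists past the camera threshold in the first 4 comparisons numbered 1, 1, 11 and 11. The estimated correlation gave 5 and 4 at 24 h, fry 2 at 100 µCi and 46 min, and mixed fry 3 at 200 µCi and 46 min and 20 and 22 at 24 h. At 46 min the lists numbered 7 and 5 with a term for the 3 arrays, 2 and 5 without them, 2 and 4 above the median level, 12 and 6 under median centring, 14 and 6 on deposited values, and 15 and 7 on deposited values without the 3 arrays.

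Leaving out each array in turn gave ranges of 15 to 81, 41 to 115, 894 to 1378, 1017 to 1454, 2 to 7, 1 to 7, 610 to 935 and 708 to 1044 genes for the 8 counts and 0 to 0 for the interaction. The overlaps ranged over 9 to 26, 733 to 1025, 10 to 55 and 25 to 60, and the lists over 1 to 5, 1 to 6, 11 to 12 and 10 to 12.

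With replicate number as a block the 8 counts were 38, 54, 1117, 1220, 3, 1, 700 and 845, the interaction 0, the overlaps 16, 821, 29 and 30 and the lists 1, 1, 11 and 11, and 14 named calls were lost. Replicate numbers did not mark pairs in the values: 14 of 50 same-numbered pairs of arrays from different groups had r above 0.1 in their deviations from group means, the median was −0.00818, and 8 of 25 arrays matched best with an array of their own number.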

Other observations

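The markers and gene groups here were fixed before the data were examined, and the comparison within the 3 arrays that stood apart was chosen after the result was seen.

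Genes of cell death went both ways at 24 h. Of 20 pro-apoptotic genes 2 and 3 were higher and 1 lower at each activity by limma (3 and 4 higher and 1 lower adjusted over the list alone; camera adjusted p 0.0573 and 0.116). CASP8, which starts the death receptor pathway, rose by 0.34 (SE 0.09) at 200 µCi. Of 12 anti-apoptotic genes 2 were higher and 1 lower at each activity (2 and 3 higher and 1 lower adjusted over the list alone; camera adjusted p 0.472 and 0.35), and BIRC5, survivin, a gene also expressed in mitosis, fell by 0.41 and 0.44 (SE 0.08), the first of these calls being lost on deposited values. Heat shock proteins had 1 of 17 higher and 2 lower at each activity (2 and 1 higher, 2 and 3 lower, adjusted over the list alone; camera adjusted p 0.82 and 0.844). DUSP5, a phosphatase of ERK and a late member of the immediate early list, rose by 1.32 and 1.60 (SE 0.13), and TOMM20, the import receptor of the mitochondrial outer membrane, fell by 1.07 and 1.39 (SE 0.22).

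Energy metabolism was split. Of 45 oxidative phosphorylation genes 7 and 8 were higher and 5 and 4 lower at 24 h (the same numbers adjusted over the list alone; camera adjusted p 0.161 and 0.35), but on deposited values 16 and 8 were higher and 0 and 2 lower. NDUFA9, a subunit of complex I, rose by 0.40 and 0.58 (SE 0.06). Of 27 glycolysis and hypoxia genes 0 were higher and 3 lower at each activity by limma (the same adjusted over the list alone; camera adjusted p 0.362 and 0.299), and MXI1, a MYC antagonist, fell by 0.39 and 0.42 (SE 0.09). Splicing factors had 2 and 1 of 36 higher and 3 and 4 lower (the same adjusted over the list alone; camera adjusted p 0.393 and 0.17), with medians of −0.09 and −0.11 that became 0.12 and 0.02 on deposited values. SNRPG, a core protein of spliceosomal particles, rose by 0.50 and 0.53 (SE 0.08).

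No differentiation or marker list passed camera's threshold at 24 h. Median changes were −0.02 and −0.02 for 23 replication-dependent histones, 0.06 and 0.13 for 6 germinal-centre genes, −0.14 and −0.16 for 10 plasma-cell genes and −0.13 and −0.07 for 5 complement regulators, with camera adjusted p of 0.461 and 0.511, 0.383 and 0.35, 0.393 and 0.223, and 0.472 and 0.673. STAP1, an adaptor of germinal-centre B cells, rose by 0.95 (SE 0.12) at 200 µCi. Markers of other cell types were −0.04 and −0.01 for 16 T-cell and NK-cell genes, −0.01 and 0.01 for 12 myeloid genes and 0.00 and −0.02 for 11 epithelial and fibroblast genes, with camera adjusted p of 0.575 and 0.844, 0.768 and 0.928, and 0.682 and 0.877. The epithelial and fibroblast list holds VIM, which was high on the 3 arrays that stood apart.

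Those 3 arrays include 1 control and 1 array of each activity at 46 min, which gives an unreplicated contrast among them. Both activities are compared with the same control array, which by itself makes their differences alike. NFKBIA was higher on the treated arrays by 2.40 and 2.48 log2, PPP1R15A by 1.79 and 1.83 and FOSB by 0.75 and 0.94. FOS differed by only 0.23 and −0.20, against 1.61 and 1.36 on the other arrays, and DUSP1 by 0.56 and 0.50, where its means on the other arrays were 7.20 in the control and 8.41 and 8.58 after treatment. CDKN1A was higher by 1.01 and 1.07 and RGS16, a regulator of G-protein signalling, by 2.20 and 2.02, against −0.07 and 0.04 and 0.35 and 0.18 on the other arrays, where neither passed. Of 29 immediate early genes 26 and 21 were higher, with medians of 0.38 and 0.37. Of the 140 and 350 genes called on the other arrays, 123 and 296 went the same way here, and across all genes, which are not independent replicates, the changes correlated at r = 0.461 and 0.436.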
